A study of Rattus norvegicus with 24 samples.

How the data were processed

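Single-cell RNA sequencing was applied to dissociated corpus cavernosum of Sprague-Dawley rats. Per the labels' protocols, tissue without the tunica was digested with collagenase, elastase and DNase, filtered, freed of red blood cells by lysis and depleted of dead cells before library preparation. These steps can change the proportions of cell types and induce early response genes. The submitters' processing notes name Cell Ranger 3.1.0, Seurat 3.2.2 and R 4.0.2 without their roles. The genome build, the annotation, the library chemistry, the filters on cells and the treatment of doublets are not given in the sources used here.

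The deposited files used were a list of cell barcodes and a list of genes (identifier, symbol and feature type). Neither holds a measured value, so no unit of expression applies, no normalisation was made and no expression test could be run. No doublet caller was run, since it needs counts. The expression matrix that these lists index was not analysed here. The tests of expression and of cell type shares that had been planned before the data were examined were conditional on counts mapped to samples, and were not run. Samples were grouped by age from their titles, 12 young and 12 old. Barcodes carry only the suffix 1 or 2, which was not matched to any sample or age by its order, so no comparison between the ages was made.

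Barcodes were counted per suffix and in distinct sequences, with Wilson 95% intervals for shares and an exact Poisson 95% interval for the number of sequences shared by both suffixes (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). The number expected by chance is the product of both set sizes divided by the size of the barcode pool. Pool sizes of 6794880 (taken for 10x Genomics v3 chemistry) and 737280 (v2) were assumed from general knowledge of these kits. They were not values from the files. A smaller pool gives a larger expected count, so each comparison with chance depends on the assumed size. The mean shared count was checked against this formula on simulated even draws with a known pool and a known number of added shared barcodes. Their pools and set sizes differed from those used here, and the Poisson interval was not tested. Intervals cover counting error only.

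Genes were named by a rule fixed before the data were examined: only members of 8 functional lists and 15 cell type marker lists, as found or not, with no expression value. The coverage of 1 functional list is included in the totals and is not reported here on its own. Mitochondrial and other gene families were described by the start of their symbols, a choice made after the gene list was seen. Gene symbols were matched exactly, then ignoring case, then only where a symbol stood on 1 row. Identifiers were not matched to the RefSeq table (assembly GRCr8), because 0 of its rows carry an Ensembl identifier. Symbols were matched to it for the gene type, and no coordinates were taken from it. Symbols held in RefSeq under another name count as unmatched.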

Results

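Cells of the rat penile corpus cavernosum, the erectile tissue built from smooth muscle, vascular spaces lined by endothelium and a collagen-rich stroma, were profiled by single-cell RNA sequencing to compare young with aged animals. The labels describe 24 samples of Sprague-Dawley rats, 12 taken at 3 months (young) and 12 at 23 months (old). The series text gives 5 rats of each age, so some of the 12 samples of an age shared an animal. No label ties a sample to a rat.

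The deposited material analysed here consisted of the list of cell barcodes and the list of genes that name the columns and rows of a filtered cell-by-gene matrix. The expression values of that matrix were not analysed here. No gene could therefore be called higher or lower with age, no cell could be assigned to a type, and no replicate error could be given for an expression level. What the lists do show is the number of cell barcodes kept in the filtered matrix and how they were divided between barcode sets. They also show which genes of interest to erectile tissue were in the gene list as analysed here.

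The matrix held 16482 cell barcodes of 16 bases each. A numeric suffix divided them into 2 sets. What the suffix stands for is not given in the sources used here. Suffix 1 had 9284 barcodes, 56.3% of all (95% Wilson interval 55.6 to 57.1%), and suffix 2 had 7198, or 43.7% (42.9 to 44.4%). These intervals cover counting error only. There were 24 labelled samples but 2 suffixes, so the barcode names do not separate the samples and show no replicates within an age. Neither suffix carries a word or number that matches the label of a single sample or age. The suffixes were therefore not assigned to young or old, and the numbers of cells were not compared between the ages. A barcode can hold more than 1 cell, and how doublets were treated is not given in the sources used here. The UMI depth per barcode is unknown.

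Within each set every barcode sequence occurred once. Across the sets, 24 sequences occurred with both suffixes (exact 95% Poisson interval 15.4 to 35.7), which was 0.259% of the barcodes with suffix 1 and 0.333% of those with suffix 2. The 16482 barcodes thus comprised 16458 distinct sequences.

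The gene list, as analysed here, had 22050 rows, each with its own rat Ensembl identifier and all of the gene expression type. They carried 21905 distinct symbols, and 134 symbols stood on more than 1 row. Of the 22050 rows, 16864 (76.5%) had a symbol that is also in the RefSeq gene table, and 99.8% of these matched rows were protein coding there. Only 10 matched rows were long non-coding RNAs in that table. A further description comes from the names themselves. Olfactory receptors (Olr) made up 1101 rows and vomeronasal receptors (Vom1r and Vom2r) 150. Names beginning with Rpl or Rps and a number, the usual form for ribosomal proteins, made up 104 rows. The mitochondrial genome contributed 13 rows (symbols beginning with Mt-). Placeholder names taken from contigs, locus numbers or database numbers accounted for 3524 rows, or 15.98%.

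The genes through which ageing of erectile tissue would be read were largely in the gene list. The same list held 1101 olfactory receptor rows, so it was not limited to genes tied to this tissue. High coverage of the functional and marker lists is therefore not a result about the tissue. Of 83 genes in 8 functional lists, 79 were found by symbol, and 5 of the 8 lists were complete. The presence of a gene in the list means that the matrix had a row for it, and carries no information on its expression. Whether its transcripts could be counted was not tested. All 10 contractile smooth muscle genes were found, including Acta2 and Myh11, which encode the smooth muscle forms of actin and myosin heavy chain, and Myocd, a transcriptional coactivator of the contractile programme. The list on nitric oxide, cyclic GMP and other erectile signalling had 12 of its 13 genes. Among them were Nos3 and Nos1, the endothelial and neuronal nitric oxide synthases, Gucy1a1 and Gucy1b1, the subunits of soluble guanylate cyclase, and Pde5a, the phosphodiesterase that degrades cyclic GMP.

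Of the extracellular matrix genes, 14 of 15 were found, including the fibrillar collagen genes Col1a1 and Col3a1, the elastin gene Eln and Lox, which encodes a collagen cross-linking enzyme. All 11 senescence and inflammation genes were found, among them the cell cycle inhibitors Cdkn1a and Cdkn2a and the cytokine gene Il6. The lists for oxidative stress defence (10 of 10 genes, including the superoxide dismutases Sod1, Sod2 and Sod3) and the cell cycle (8 of 8, including Mki67 and Top2a) were complete. For the early response to tissue dissociation, 8 of 10 genes were found, including Fos, Jun and Egr1.

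Markers of the cell types that the tissue or its dissection could hold were found for 71 of 75 distinct genes, and 11 of 15 marker lists were complete. All 6 smooth muscle markers and all 6 pericyte markers, including Rgs5, Kcnj8 and Pdgfrb, were found. The endothelial list had 6 of its 7 genes, including Cdh5, Vwf and Kdr, and the lymphatic endothelial list had all 5, including Prox1 and Lyve1. The fibroblast list had 5 of 6, including Pdgfra and Dcn. Among immune cells, macrophage (6 of 6 genes), B cell (4 of 4), neutrophil (4 of 4) and mast cell (4 of 4) markers were complete, and the T cell list had 4 of 5. Schwann cell (5 of 5), epithelial (6 of 6), chondrocyte (4 of 4) and red blood cell (3 of 3) markers were also complete, and 3 of 4 skeletal muscle markers were found. Over both kinds of list, 143 of 150 distinct genes were found. The other 7 were looked up and matched no symbol in the gene list as analysed here. Whether they were part of the authors' annotation is not known, so the coverage counts describe this list and not that annotation.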

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

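Counting only barcode sequences found with a single suffix left 9260 barcodes for suffix 1 and 7174 for suffix 2, each within 1.5 times the full count. Only the 24 shared sequences were removed from each set, so this limit could not have been exceeded. The number of shared sequences lay above chance for the larger barcode pool, the size assumed for v3, at a log2 ratio of 1.29. It lay below chance for the smaller (v2) pool, at -1.92. The pool size alone sets this reversal, since the observed count is 24 in both. Ignoring case in symbols, or using only symbols that occur once, left 79 functional list genes and 71 marker genes found, as with the exact match. Leaving out the suffix with the most barcodes gave no value, because 1 set has no partner to share with. No paired analysis was possible because the barcodes carry no sample or replicate number and no value per sample was available. Alternatives for expression, cell type shares and barcodes per sample, including leaving out each sample, were not run for the same reason. Depth could not be assessed without counts.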

Other observations

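The comparison of the shared count with chance was not among the tests fixed before the data were examined. The test of the upper bound of that count against the v2 value was chosen after the count had been seen. The 24 barcode sequences found with both suffixes were 2.44 times the 9.83 expected if both sets were random draws from the larger v3 pool (95% interval of the ratio 1.56 to 3.63). Even random draws from the smaller v2 pool would give 90.6, and the upper bound of the observed count, 35.7, lies below this. This argues against even draws from the v2 pool and leaves open draws that used it unevenly, differently in each set. The excess over the v3 value was not resolved either, since it depends on the assumed pool size. A v3 pool smaller than assumed would lower the ratio and could remove the excess, and was not tested. Uneven use of the pool and reads carried between libraries during sequencing were not tested, because telling them apart needs the UMI counts behind each shared barcode. No biological explanation was tested.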
